A study of Mus musculus with 12 samples.

How the data were processed

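Gene expression was measured in total RNA from mouse heart muscle on 12 Affymetrix arrays of the MOE430A design, 3 for each of 4 groups, which were control and mdx hearts at 8 weeks and at 10.5 months. The groups and replicate numbers were taken from the sample titles. A keyword in the sample records names extraocular muscle instead of heart, and nothing in the labels explains it. The deposited values were intensity on a linear scale, 1 value per probe set and array for 22690 probe sets, running from 0.3 to 210298. The authors had already scaled the arrays to a common target, because the trimmed mean (2% left off at each end) lay between 1500.6 and 1500.9 on every array. Per the labels, a standard Affymetrix protocol was used. The software that combined the probes of a probe set, its version and any detection calls were not given in the sources used here. No column was left without a sample.

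Probe sets were named through the platform annotation given with the values. It paired 20393 probe sets with 1 gene, 691 with several and 1606 with none, and 20364 symbols were matched or updated through current gene tables. No gene was named from a probe set with several genes. Some symbols differ from those in use when the arrays were designed.

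Each array was rescaled to a trimmed mean of 500, and the analysis used log2(signal + 32). The offset equals 96 deposited units. A fold change on this scale understates the change of dim genes. The 64 Affymetrix control probe sets were left out, and probe sets with a mean scaled signal of at least 100 over the 12 arrays (300 deposited units) were tested. This left 14932 probe sets, of which 13722 had 1 gene, for 8852 genes. In R 4.3.3, limma 3.58.1 fitted a mean per group to all 12 arrays (lmFit and eBayes), so that the 4 groups shared 1 estimate of the spread with 8 residual and 5.2 prior degrees of freedom. The median SD of log2 signal within a group was 0.202 and 0.250 for control and mdx hearts at 8 weeks. At 10.5 months it was 0.147 and 0.193. A shared estimate thus tends to be too small for the 8-week comparison and too large for the 10.5-month one. There were 6 comparisons, which were mdx against control at each age, their mean, their difference, and age within control and within mdx hearts. Adjusted p-values are Benjamini-Hochberg values over the tested probe sets, and an adjusted p below 0.05 was called a change. Errors of fold changes are standard errors of the fit, and levels are means ± SD of the scaled signal over 3 arrays.

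The 38 gene lists, 23 of pathways and 15 of cell types or tissues, were written down before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes. The pathway lists covered the dystrophin glycoprotein complex, integrins and costameres, the sarcomere, hypertrophy and the fetal programme, extracellular matrix and fibrosis, complement, antigen presentation, the interferon response, chemokines and cytokines, fatty acid oxidation, glycolysis and glucose use, oxidative phosphorylation, calcium handling, ion channels and conduction, neurohormonal signalling, heat shock and chaperones, antioxidants and metallothioneins, p53 targets with cell death and senescence, atrophy and autophagy, the cell cycle, skeletal muscle regeneration, the circadian clock and immediate early genes. The others held markers of macrophages and monocytes, lymphocytes, granulocytes and mast cells, fibroblasts, endothelium, smooth muscle and pericytes, atrial myocytes, ventricular myocytes, fast skeletal muscle, adipocytes, erythroid cells, lung, thymus and lymph node, nerve and Schwann cells, and the sex of the animal. Some lists share members, so their calls are not independent. Nppa and Myl4 are in the hypertrophy and atrial lists, and Ccn2 is in the hypertrophy and matrix lists. Dcn, Lum, Col1a1, Col1a2 and Col3a1 are in the matrix and fibroblast lists. The ventricular list shares Kcnd2 and Kcnip2 with ion channels, and Myl2, Myl3 and Myh6 with the sarcomere. Each gene was represented by its brightest probe set. Lists with at least 4 measured members were compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes, adjusted over the 35 lists tested. Camera with a correlation estimated per list, and fry, which tests the direction of a list on its own, were alternatives. In no called list did the median, the mean and the test differ in sign.

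For mdx at each age and for age in controls, the genes named are the 10 largest rises and the 10 largest falls among called probe sets that were the brightest of their gene, or all where fewer passed. For the remaining comparisons 5 were taken in each direction. Genes without a proper symbol were passed over, and Dmd and Utrn are always given. From each list described, up to 4 members with the smallest p-value among those called over all probe sets or over the list alone are named, or otherwise the member with the smallest p-value. Arntl at 10.5 months was added to the clock genes after seeing the data, as the only clock gene with a positive value that passed adjusted over the list alone.

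The computation was tested on simulated arrays with the real means and spreads, in which 50 probe sets were changed by each of several sizes. For mdx at 8 weeks it recovered 16% of changes of 0.6 on the log2 scale, 50% of changes of 1, 94% of 1.5 and 96% of 2, with 5 false calls among 133. For mdx at 10.5 months these shares were 12%, 68%, 98% and 100%, with 6 false calls among 145, and for age in controls they were 20%, 56%, 86% and 92%, with 5 among 132. A simulated shift of 0.5 in the matrix list was called, and 0 of the other lists were. The simulated probe sets were drawn independently of each other, so this does not test list calls among genes that move together.

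Alternatives fixed in advance were quantile normalization, an offset of 16 or a floor of 64 before the logarithm, no filter or a filter at 300, eBayes with trend and robust, array quality weights, a fit of only the groups compared, the replicate number as a block, each array left out in turn, other thresholds, and other list tests. A block for arrays with a wide signal range, an atrial score as a covariate, and the removal of 2 control arrays with high atrial markers were added after seeing the data. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The sex of the animals, the time of day of collection and array processing batches were not given in the sources used here.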

Results

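Expression was compared in heart muscle of mdx mice, which carry a mutation in the dystrophin gene Dmd and are the standard mouse model of Duchenne muscular dystrophy, and of wild-type controls. Young hearts at 8 weeks and older hearts at 10.5 months were each represented by 3 mdx and 3 control arrays. The sample records also carry a keyword that names extraocular muscle, so the tissue rests on their source and titles, which name heart. The deposited median signal per array lay between 532.8 and 665.8 units. Correlations of log2 signal were 0.948 to 0.982 between replicates of a group, and 0.923 to 0.958 between an 8-week mdx array and an array of another group. On 4 arrays the brightest probe sets reached further than on the remaining 8. The 99th percentile of deposited signal was 43094 for control replicate 2 at 8 weeks, 53154 and 45663 for mdx replicates 1 and 2 at 8 weeks, and 40770 for mdx replicate 3 at 10.5 months, against at most 32810 elsewhere. Control probe sets at the 2 ends of a transcript bear on RNA quality. Their actin ratio was highest on mdx replicate 3 at 10.5 months (1.44, at most 1.289 elsewhere). The Gapdh ratio was highest on mdx replicate 1 at 8 weeks (0.973, at most 0.845 elsewhere). Both arrays also had the wide signal range, so on these 2 arrays the traits cannot be told apart. The other wide arrays, control and mdx replicates 2 at 8 weeks, had no raised ratio (actin 1.158 and 1.133, Gapdh 0.7785 and 0.7553).

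Dmd was lower on all 6 mdx arrays than on all 6 control arrays. Its brightest probe set gave signals of 607, 780 and 623 in controls and 264, 279 and 159 in mdx hearts at 8 weeks. At 10.5 months it gave 839, 839 and 796 in controls and 264, 286 and 195 in mdx hearts. On the log2 scale Dmd fell by 1.42 ± 0.20 at 8 weeks (adjusted p = 0.00596) and by 1.63 ± 0.20 at 10.5 months (adjusted p = 0.0120), and the 2 falls were not shown to differ (difference -0.20 ± 0.28, adjusted p = 0.824). The other tested probe set of Dmd fell by 1.204 and by 1.88 (adjusted p = 0.0103 and 0.00221). The mdx mutation is a point mutation, so these probe sets measure the level of the transcript and not the mutation itself. Utrn, which encodes the dystrophin homologue utrophin, did not pass the test at either age (-0.10 ± 0.16, adjusted p = 0.793, and -0.33 ± 0.16, adjusted p = 0.677), and at 8 weeks it was at 0.02 without control replicate 3. Of the 14 measured genes of the dystrophin glycoprotein complex only Dmd passed over all probe sets at each age. Adjusted over the list alone, the syntrophin gene Sntb1 (0.97 ± 0.27) and the sarcoglycan gene Sgca (-0.50 ± 0.15) also passed at 8 weeks, and no other member did at 10.5 months.

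**Figure D1:**
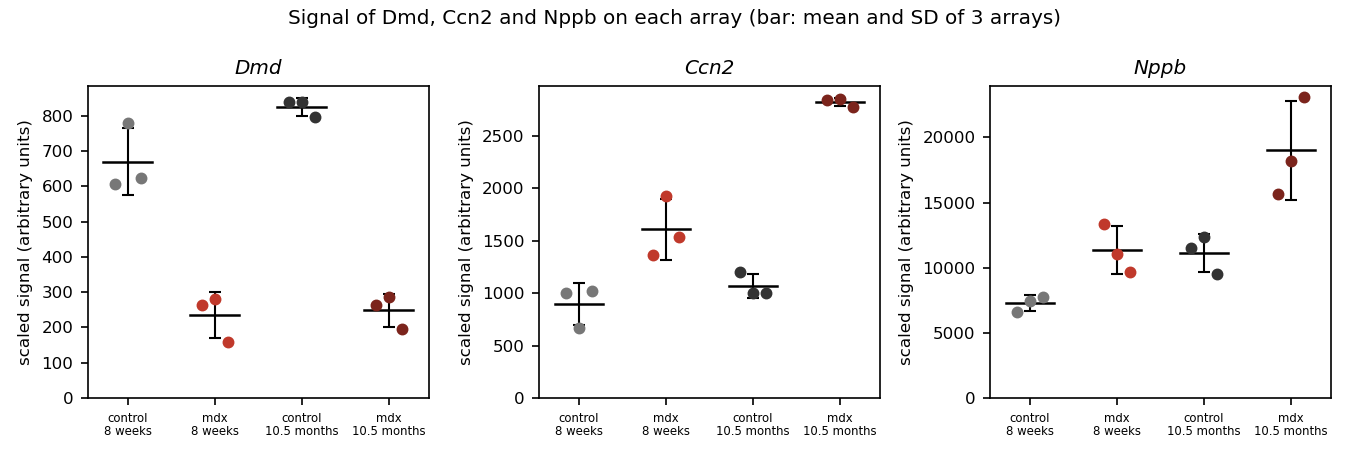
Scaled signal (arbitrary units) of Dmd, Ccn2 and Nppb on each of the 12 arrays, in the 4 groups, with the mean and SD of 3 arrays as bars. Dmd lies between 159 and 286 in mdx hearts and between 607 and 839 in controls, and Ccn2 at 10.5 months lies between 2780 and 2855 in mdx hearts and between 1003 and 1199 in controls.

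At 8 weeks the question was what differed in young mdx heart. Interferon-inducible GTPases, which act in defence against intracellular pathogens, were among the genes with the largest rise. Iigp1 rose from 3975 ± 833 to 12678 ± 3411, 3.15-fold (log2 1.65 ± 0.24, adjusted p = 0.00596), Irgm2 rose 2.72-fold (1.45 ± 0.29, adjusted p = 0.0292) and Igtp rose by 1.23 ± 0.24 on the log2 scale (adjusted p = 0.0263). Ifi27l2b, of another interferon-induced family, rose 3.15-fold (1.66 ± 0.26, adjusted p = 0.00979). Ccn2, a matrix-associated growth factor linked to fibrosis, rose by 0.83 ± 0.18 (adjusted p = 0.0392). The skeletal actin gene Acta1 fell by 1.199 ± 0.230 (adjusted p = 0.0251) and the smooth muscle actin gene Acta2 by 0.80 ± 0.14 (adjusted p = 0.0184).

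The remaining genes with the largest changes at 8 weeks belonged to no list, and most were dim. The largest rise was of Tvp23a, from 61.8 ± 11.3 to 415 ± 87.3 (log2 2.24 ± 0.39, adjusted p = 0.0163), followed by Telo2, which helps to stabilise large kinases of the DNA damage response (1.71). Next came Rassf1 (1.66), the splicing factor gene Prpf40b (1.63), the histamine receptor gene Hrh2 (1.49), the myosin gene Myo7b (1.43) and the BAFF receptor gene Tnfrsf13c (1.41), with adjusted p between 0.0163 and 0.0476. Among the largest falls were those of the poly(A) polymerase gene Tent5c (-2.25 ± 0.48, adjusted p = 0.0349) and of P2ry1, a receptor for ADP (-1.99 ± 0.21, adjusted p = 0.00100), from 183 ± 63.6 to a signal below the offset (20.6 ± 6.4). The size for P2ry1 therefore depends on the offset, with -2.41 at an offset of 16 and -1.45 with a floor of 64. Ntmt1, Agpat5, Pdlim4, Drg2, Lhpp, Nbeal2, Txndc11 and Drc3 fell by 1.45 to 1.67 (adjusted p = 0.00100 to 0.0474). The median signal of the called probe sets was 259, against 385 for those tested.

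Of 35 lists tested at 8 weeks, 4 were higher in mdx hearts by camera, and 0 held with an estimated correlation or by fry. In the interferon response list 17 of 19 genes had positive values, with a median of 0.49 (adjusted p = 0.00760, adjusted p = 0.867 with an estimated correlation). Igtp passed over all probe sets, and Igtp and the antiviral membrane protein gene Ifitm3 (0.61 ± 0.17) passed when adjusted over the list alone. This call was lost without mdx replicate 3 (median 0.16, adjusted p = 0.254). In the list of chemokines and cytokines 14 of 18 genes had positive values (median 0.35, adjusted p = 0.0494, adjusted p = 0.867 with an estimated correlation), and no member passed over all probe sets or when adjusted over the list alone. Cxcl14 came nearest (0.74 ± 0.21, adjusted p = 0.0842). The list kept its call in 11 of 21 alternatives. It lost it without control replicate 2 or 3, without mdx replicate 1 or 3 at 8 weeks, and without mdx replicate 2 or 3 at 10.5 months (adjusted p = 0.131, 0.142, 0.0580, 0.410, 0.0538 and 0.0558). It was also lost after quantile normalization (0.0504) and with no filter (median 0.23, adjusted p = 0.0747), and the median rose to 0.53 without mdx replicate 2.

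Sarcomere genes and oxidative phosphorylation genes had medians of 0.33 (18 of 19 positive) and 0.22 (51 of 56 positive) at 8 weeks, but -0.02 and -0.08 after quantile normalization. Both lists were called without it (adjusted p = 0.0255 and 0.0255, adjusted p = 0.867 and 0.867 with an estimated correlation), and no member passed over all probe sets or adjusted over the list alone. Ttn (0.76 ± 0.30) and Atp5pb (0.83 ± 0.24) came nearest in each. These are among the brightest probe sets on the arrays, and 2 of 3 mdx arrays but 1 of 3 control arrays at 8 weeks had the wide signal range. With the signal range as a block the medians were 0.06 (adjusted p = 0.459) and -0.01 (adjusted p = 0.768). Without mdx replicate 1 they were 0.00 (adjusted p = 0.767) and -0.02 (adjusted p = 0.874), and without mdx replicate 2 they were 0.22 (0.264) and 0.13 (0.534). Without control replicate 1 they were 0.18 (0.396) and 0.09 (0.603), and without control replicate 3 they were 0.20 (0.174) and 0.15 (0.275). With no filter the adjusted p were 0.0721 and 0.0971, and with the mean of a gene's probe sets the sarcomere list had 0.0514. Other single arrays raised the medians, to 0.61 and 0.45 without control replicate 2 and to 0.71 and 0.56 without mdx replicate 3.

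Among lists not called at 8 weeks, the 10 measured hypertrophy and fetal genes had 1 member higher and 1 lower over all probe sets (Ccn2 and Acta1). Adjusted over the list alone 4 were higher and 1 lower, which added the natriuretic peptide gene Nppa (1.25 ± 0.31, adjusted p = 0.0548) and the stress-responsive gene Ankrd1 (0.88 ± 0.25, adjusted p = 0.0848). Atrial markers differed in the same direction, with Myl7 at 567 to 895 in mdx hearts and 239 to 476 in controls. Of 42 extracellular matrix genes 2 passed (Ccn2, and Col16a1 at 1.22 ± 0.29, adjusted p = 0.0490). Adjusted over the list alone 4 were higher and 1 lower, among them Col8a1 (0.77 ± 0.20) and Mmp14 (0.76 ± 0.23). Single members of other lists rose, namely the calcium release channel gene Itpr2 (1.34 ± 0.24, adjusted p = 0.0169), the natriuretic peptide protease gene Corin (0.80 ± 0.18, adjusted p = 0.0407), Casp12 (0.72 ± 0.17, adjusted p = 0.0474) and the glial factor gene Sox10 (0.95 ± 0.21, adjusted p = 0.0365). Others fell, namely the potassium channel gene Kcna5 (-1.10 ± 0.19, adjusted p = 0.0173), the replication gene Mcm3 (-1.17 ± 0.26, adjusted p = 0.0393), Klf15 (-0.91 ± 0.20, adjusted p = 0.0383), the protease gene Capn1 (-0.91 ± 0.22, adjusted p = 0.0490), Hsph1 (-0.75 ± 0.17, adjusted p = 0.0467) and Smtn (-0.69 ± 0.16, adjusted p = 0.0467).

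**Figure D2:**
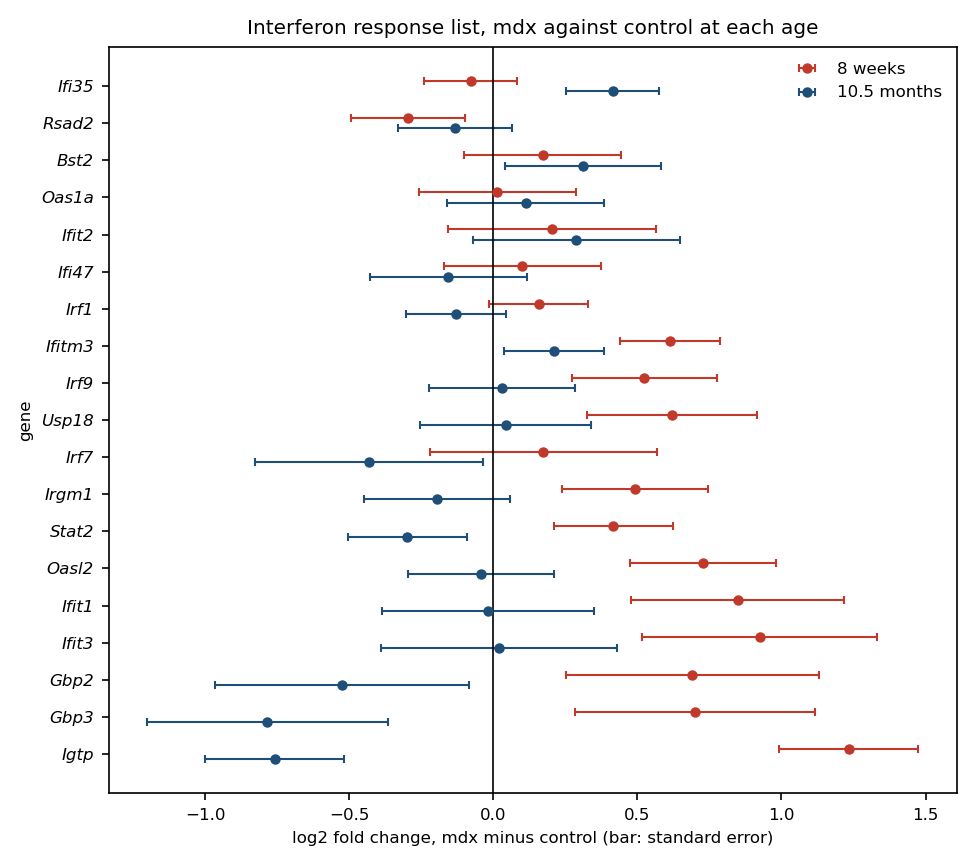
Log2 fold change of each measured gene of the interferon response list, mdx minus control, at 8 weeks and at 10.5 months, with standard errors of the fit as bars. Igtp is at 1.23 at 8 weeks and at -0.76 at 10.5 months, and 17 of 19 genes are above 0 at 8 weeks against 8 of 19 at 10.5 months.

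In all, limma called 343 probe sets at 8 weeks, 207 higher and 136 lower, for 309 genes, of which 71 and 71 changed at least 2-fold. At an unadjusted p below 0.05 there were 2661, against 747 by chance. Of 171 called genes with another tested probe set, the brightest of the others moved in the same direction in 111 (share 0.649, exact 95% interval 0.573 to 0.720), and in 6 it was called too. The called probe sets had a median size of change of 0.914, and these others moved by a median of 0.11 in the called direction. The called probe sets were picked by their p-value, which favours large changes, so part of this gap may come from selection. Over the 3206 genes with at least 2 tested probe sets, changes of the 2 brightest correlated with r = 0.17, against 0.474 at 10.5 months. The count was 95 and 42 without control replicates 1 and 3 and 212 without mdx replicate 3. It was 164, 161, 210 and 167 without control replicates 1, 2 and 3 and mdx replicate 2 at 10.5 months, and 23 when only the 8-week arrays were fitted.

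At 10.5 months the question was what differed in older mdx heart, and 6 genes changed. Ccn2 rose from 1069 ± 113 to 2827 ± 40.8, 2.61-fold (log2 1.38 ± 0.18, adjusted p = 0.0121), and Ndrg4, which is expressed in heart and nerve, rose 2.15-fold (1.11 ± 0.14, adjusted p = 0.0121). Dbp and Tef, transcription factors driven by the circadian clock, fell by 2.001 ± 0.282 and by 1.31 ± 0.20 (adjusted p = 0.0184 and 0.0414), and Dbp went from 1480 ± 389 to 346 ± 98.9. Tob2, an antiproliferative regulator, fell by 1.47 ± 0.19 (adjusted p = 0.0121), and Dmd was the sixth gene.

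Camera called 10 of the 35 lists tested at 10.5 months, against 0 with an estimated correlation and 1 by fry, the clock list. Genes of matrix, fibroblasts and macrophages were higher as groups by camera. Of 42 extracellular matrix genes 33 had positive values (median 0.22, adjusted p = 4.63e-07, adjusted p = 0.426 with an estimated correlation). Over all probe sets 1 passed, and 6 passed adjusted over the list alone. Among these were Ccn2, the cartilage matrix gene Comp (1.05 ± 0.23), the proteoglycan gene Lum (0.78 ± 0.19) and Tgfb2 (0.87 ± 0.22). Of 15 fibroblast genes 13 were positive (median 0.24, adjusted p = 1.20e-04, adjusted p = 0.426 with an estimated correlation). By limma 0 passed over all probe sets, while Mfap5 (0.98 ± 0.23), Lum and Dpt (0.62 ± 0.17) passed adjusted over the list alone. Of 26 macrophage and monocyte genes 24 were positive (median 0.29, adjusted p = 3.35e-05, adjusted p = 0.551 with an estimated correlation). None passed on its own, with Tyrobp nearest (0.75 ± 0.31, adjusted p = 0.666), and the median was 0.18 without control replicate 3. Of 8 complement genes 7 were positive (median 0.32, adjusted p = 0.00323, adjusted p = 0.426 with an estimated correlation), with the inhibitor gene Serping1 (0.64 ± 0.18) passing adjusted over the list alone. This call was lost without mdx replicate 3 (median 0.11, adjusted p = 0.101), and the median was 0.19 without control replicate 1.

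Genes of hypertrophy and the fetal programme were higher too (7 of 10 positive, median 0.29, adjusted p = 0.00106, adjusted p = 0.417 with an estimated correlation). Ccn2 passed over all probe sets, and Ccn2, Nppb (0.76 ± 0.18) and the calcineurin regulator gene Rcan1 (0.64 ± 0.17) passed adjusted over the list alone. The call was lost without control replicate 3 (median 0.14, adjusted p = 0.0862), and the median was 0.17 without mdx replicate 2. Oxidative phosphorylation genes had a median of 0.26 (51 of 56 positive, adjusted p = 3.35e-05, adjusted p = 0.752 with an estimated correlation), which was 0.02 after quantile normalization (adjusted p = 0.997) and 0.01 with the signal range as a block (adjusted p = 0.952). No member passed, with Ndufs4 nearest (0.36 ± 0.18), and mdx replicate 3, the array of wide signal range and highest actin ratio in this comparison, decided the call (median 0.13 and adjusted p = 0.122 without it).

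Circadian clock genes were lower at 10.5 months, with 10 of 13 negative (median -0.88, adjusted p = 5.13e-09, adjusted p = 0.121 with an estimated correlation, adjusted p = 0.00673 by fry). Dbp and Tef passed over all probe sets. Adjusted over the list alone 7 genes were lower, among them Per3 (-0.88 ± 0.14) and Hlf (-0.95 ± 0.16). Of the 3 genes with positive values the core clock gene Arntl (0.84 ± 0.22) was the only 1 to pass. Each of these calls rests on hearts whose time of collection is unknown. At 8 weeks the same list had a median of -0.17 (adjusted p = 0.510), Dbp was at -0.78 ± 0.28 and Arntl at 0.53 ± 0.22, and none of its members passed.

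**Figure D3:**
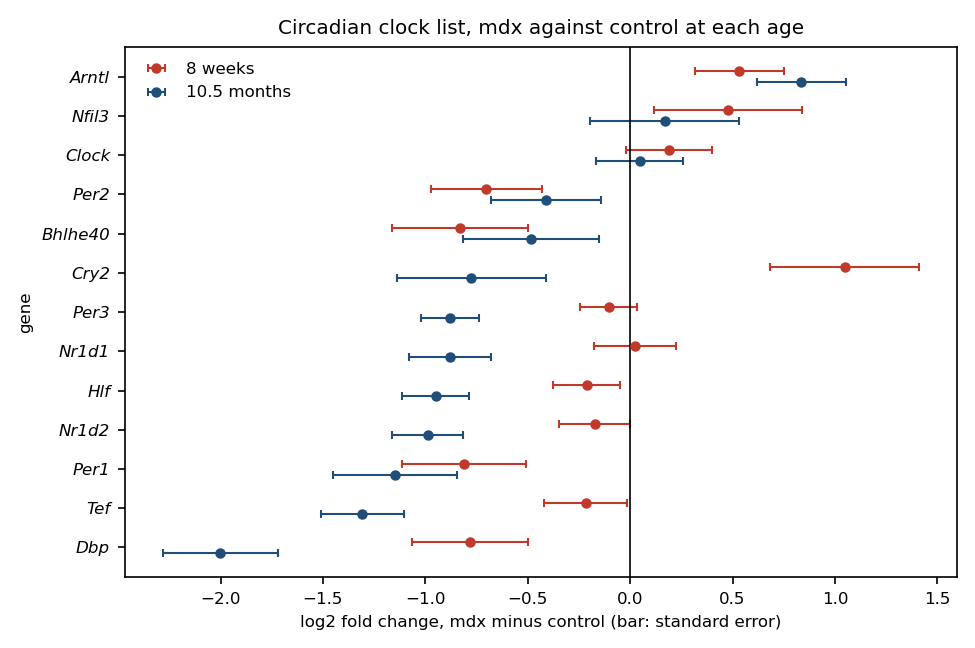
Log2 fold change of each measured circadian clock gene, mdx minus control, at 8 weeks and at 10.5 months, with standard errors of the fit as bars. At 10.5 months Dbp is lowest at -2.001 and Arntl highest at 0.84, and 10 of 13 genes are below 0, against 8 of 13 at 8 weeks.

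Markers of endothelium (13 of 16 negative, median -0.26, adjusted p = 0.00860, adjusted p = 0.585 with an estimated correlation) and ion channels (12 of 16 negative, median -0.19, adjusted p = 0.00323, adjusted p = 0.426 with an estimated correlation) were lower at 10.5 months. No member of either passed, and Vwf (-0.59 ± 0.21) and the potassium channel gene Kcnd2 (-0.55 ± 0.15) came nearest. Without mdx replicate 3 the medians were -0.18 and -0.09 (adjusted p = 0.122 and 0.0876). Without control replicate 2 the endothelial median was -0.21 (adjusted p = 0.0591). Without mdx replicate 1 the ion channel median was -0.28. Atrial myocyte markers were lower in mdx hearts (7 of 8 negative, median -0.75, adjusted p = 0.00323, adjusted p = 0.551 with an estimated correlation), with no member passing. This came from 2 control arrays. Myl7 was 3554 and 2216 in control replicates 1 and 2, 131 in control replicate 3, and 270, 151 and 284 in mdx hearts. Sln, which is also expressed mainly in atria, was 2242, 1220 and 9.1 in controls and 25.5, 11.8 and 91.6 in mdx hearts. Without control replicate 1 the list had a median of -0.39 (adjusted p = 0.273), and without control replicate 3 one of -1.48. Without replicates 1 and 2 it was 0.69 (adjusted p = 0.00189), but this sets 3 mdx arrays against 1 control array, with the spread taken from the other groups, and so shows only what replicate 3 holds. With the atrial score as a covariate it was 0.00 (adjusted p = 0.386). Against that 1 array the endothelial and ion channel lists had medians of -0.20 and -0.21 (adjusted p = 0.0865 and 0.0511), and with the covariate they kept their calls (adjusted p = 0.0278 and 0.0203). The matrix, fibroblast, macrophage, complement, hypertrophy and clock lists kept theirs with the covariate.

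**Figure D4:**
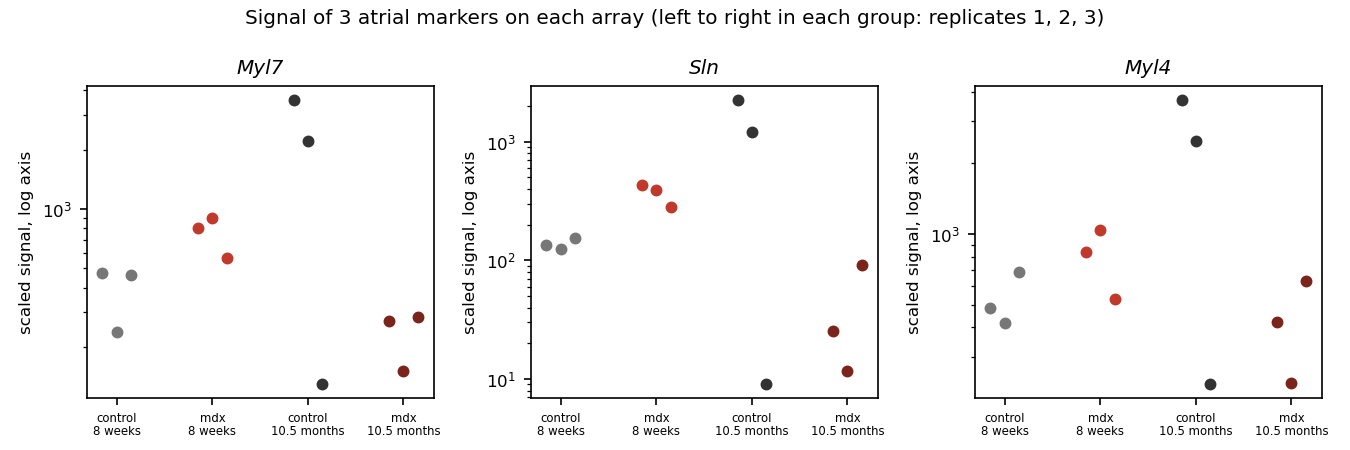
Scaled signal (arbitrary units, logarithmic axes) of the atrial markers Myl7, Sln and Myl4 on each of the 12 arrays, 1 point per array. Control replicates 1 and 2 at 10.5 months lie highest in each panel, and control replicate 3 lies lowest.

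In all, limma called 7 probe sets at 10.5 months, 2 higher and 5 lower, and 1100 had an unadjusted p below 0.05, against 747 by chance. The count was 1 and 1 without control replicates 1 and 2, 0 without both, and 0 with the atrial score as a covariate. It was 2 and 2 without mdx replicates 2 and 3, and 12 without mdx replicate 3 at 8 weeks. The 6 genes kept their direction in every alternative. With the covariate Dmd still had -1.61 ± 0.26 and Ccn2 1.496 ± 0.230, with larger errors (adjusted p = 0.0678 and 0.0677).

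Averaged over both ages, Ccn2 rose by 1.11 ± 0.13 (adjusted p = 0.00426), Kifc2 by 0.99 ± 0.18 (adjusted p = 0.0487), Ndrg4 by 0.74 ± 0.10 (adjusted p = 0.00754), the mitochondrial folate enzyme gene Mthfd2 by 0.70 ± 0.12 (adjusted p = 0.0301) and Wdr75 by 0.57 ± 0.10 (adjusted p = 0.0435). Dmd (-1.52 ± 0.14, adjusted p = 4.57e-04), Dbp (-1.39 ± 0.20, adjusted p = 0.0110), Tob2 (-1.13 ± 0.14, adjusted p = 0.00426), P2ry1 (-1.11 ± 0.15, adjusted p = 0.00753) and Pdlim4 (-1.03 ± 0.16, adjusted p = 0.0187) fell, and with a floor of 64 P2ry1 was at -0.85 and no longer passed (adjusted p = 0.0548). The P2ry1 fall was mainly an 8-week change. At 10.5 months its signal was 239 ± 33.0 in controls and 201 ± 34.0 in mdx hearts. Utrn was at -0.21 ± 0.11 (adjusted p = 0.416). Of the 10 hypertrophy genes 1 was called over all probe sets, and 5 were higher and 1 lower adjusted over the list alone, among them Nppb (0.70 ± 0.13), Nppa (1.01 ± 0.22) and Ankrd1 (0.69 ± 0.17). Among controls at 10.5 months Nppa followed the atrial markers, at 12705 and 10540 in replicates 1 and 2 and 4555 in replicate 3, whereas in mdx hearts, with Myl7 at 151 to 284, Nppa was 10868 to 17080. Of 42 matrix genes 1 was called, and 11 were higher and 1 lower adjusted over the list alone, with Comp (0.79 ± 0.16), Tgfb2 (0.67 ± 0.16) and Col8a1 (0.55 ± 0.14) next to Ccn2.

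Over both ages 10 lists passed, 8 higher and 2 lower, and 0 passed with an estimated correlation or by fry. Higher were matrix (median 0.22, adjusted p = 3.33e-05), hypertrophy (0.29, adjusted p = 0.00332), macrophages (0.25, adjusted p = 0.00111), fibroblasts (0.21, adjusted p = 0.00376), the interferon response (0.17, adjusted p = 0.0240) and chemokines (0.26, adjusted p = 0.0152). Lower were the clock (-0.56, adjusted p = 5.30e-05) and endothelium (-0.21, adjusted p = 0.00166). With an estimated correlation these had adjusted p = 0.617 to 0.759. Besides the matrix and hypertrophy genes, only the clock gene Dbp passed over all probe sets. Adjusted over the list alone 1 clock gene was higher and 9 were lower, among them Dbp, Tef (-0.76 ± 0.14), Hlf (-0.58 ± 0.12) and Per3 (-0.49 ± 0.10). In the same way Mfap5 (0.65 ± 0.17) and Cxcl14 (0.60 ± 0.15) were higher and the endothelial receptor gene Tie1 (-0.41 ± 0.10) was lower. No macrophage or interferon gene passed, with Cd163 (-0.66 ± 0.19) and Ifitm3 (0.41 ± 0.12) nearest. Oxidative phosphorylation (0.25, adjusted p = 1.51e-05) and sarcomere genes (0.26, adjusted p = 0.00332) passed as well, each with adjusted p = 0.759 with an estimated correlation, and both turned to -0.02 after quantile normalization. With the signal range as a block they were at 0.00 and 0.01 (adjusted p = 0.828 for each). The interferon value over both ages came mainly from 8 weeks. Its median was 0.49 at that age, and its mdx effect was lower at 10.5 months (median difference -0.58). The interferon call was lost without control replicate 2 or mdx replicate 3 at 8 weeks and without control replicate 1 or mdx replicate 3 at 10.5 months (adjusted p = 0.0551, 0.428, 0.314 and 0.257). It was also lost with the atrial covariate (median 0.10, adjusted p = 0.237) and without both atrial-rich controls (median 0.02, adjusted p = 0.653). The chemokine call was lost without mdx replicate 3 at 8 weeks or control replicate 1 at 10.5 months (adjusted p = 0.144 and 0.0633) and without both atrial-rich controls (median 0.16, adjusted p = 0.0656), and the sarcomere call without control or mdx replicate 1 at 8 weeks (adjusted p = 0.0677 and 0.209). Lists that kept their calls moved too. The fibroblast median was 0.12 without control replicate 2 at 8 weeks and the macrophage median 0.14 without mdx replicate 3 at 8 weeks, and the interferon median was 0.29 without mdx replicate 2 at 8 weeks. Oxidative phosphorylation genes ranged from 0.11 without mdx replicate 1 to 0.40 without mdx replicate 3 at 8 weeks, and sarcomere genes reached 0.47 without the latter. In all 30 probe sets were called, 9 higher and 21 lower, and 2037 had an unadjusted p below 0.05. The count was 17 without control replicate 3 and 60 and 47 without mdx replicates 2 and 3 at 8 weeks. It was 12 and 16 without control replicates 1 and 2 and 14 without mdx replicate 3 at 10.5 months, and 8 without both atrial-rich controls, where 1 control array is left at 10.5 months.

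The effect of mdx was then compared between ages. Of the interferon-inducible GTPase genes named above, Iigp1 and Igtp had lower effects at 10.5 months than at 8 weeks by -2.37 ± 0.34 and -1.99 ± 0.34 (adjusted p = 0.0196 and 0.0427), and Irgm2 did not pass (-2.18 ± 0.41, adjusted p = 0.0662). At 10.5 months Igtp itself was at -0.76 ± 0.24 (adjusted p = 0.571). Prpf40b (-2.76 ± 0.46), Aanat (-2.04 ± 0.29) and Six3 (-1.64 ± 0.27) differed in the same direction. Acta2 differed the other way (1.44 ± 0.20, adjusted p = 0.0196), having fallen at 8 weeks and being at 0.64 ± 0.14 at 10.5 months (adjusted p = 0.286). So did Tpd52l1 (1.83 ± 0.31), P2ry1 (1.77 ± 0.29), the DNA glycosylase gene Mpg (1.505 ± 0.195) and Ints3 (1.47 ± 0.25), all with adjusted p between 0.0196 and 0.0427. P2ry1 and Mpg had signals below the offset in 8-week mdx hearts, and with a floor of 64 neither passed (1.1997 and 1.04, adjusted p = 0.166 and 0.0836). Only 7 of the 10 genes named for a called difference passed with that floor. In all 23 probe sets differed, 8 upward and 15 downward, or 14 and 15 after quantile normalization, and 1813 had an unadjusted p below 0.05. The count was 10 and 0 without control replicates 1 and 3 at 8 weeks, and 13 and 1 without control replicates 1 and 2 at 10.5 months. It was 4, 2 and 10 without mdx replicates 1, 2 and 3 at 10.5 months, and 4 without both atrial-rich controls.

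The lists for the interferon response (median -0.58, adjusted p = 0.0137), the clock (-0.74, adjusted p = 0.00424) and atrial markers (-1.15, adjusted p = 0.00651) differed downward between ages, and the cell cycle (0.13, adjusted p = 0.0444) upward, with adjusted p = 0.911 for each with an estimated correlation. By fry 0 lists passed for this difference. Over all probe sets 1 interferon gene, 0 clock genes, 0 atrial and 0 cell cycle genes passed by limma, against 1, 7, 0 and 0 adjusted over the list alone. The clock genes were Per3 (-0.77 ± 0.20), Tef (-1.09 ± 0.29), Cry2 (-1.82 ± 0.51) and Nr1d2 (-0.82 ± 0.25) among others. The interferon call was lost without mdx replicate 3 at 8 weeks, control replicate 3 or mdx replicate 1 at 10.5 months (adjusted p = 0.118, 0.172 and 0.142). The medians were then -0.26, -0.42 and -0.32. The cell cycle call was kept in only 9 of 21 alternatives, with medians of 0.04 to 0.24 without single arrays. It was lost without control or mdx replicate 2 at 8 weeks (adjusted p = 0.0860 and 0.199), and without control replicate 1 or 3 or mdx replicate 2 or 3 at 10.5 months (0.118, 0.101, 0.143 and 0.123). It was also lost with the range block, the atrial covariate, without the atrial-rich controls, and with the mean of a gene's probe sets (0.0576, 0.126, 0.0647 and 0.107). The atrial call was lost without control replicate 1 at 10.5 months (median -0.64, adjusted p = 0.110), and the median was -1.89 without control replicate 3. It was also lost with the atrial covariate (0.05, adjusted p = 0.890) and without both atrial-rich controls (-7.83e-06, adjusted p = 0.939). Across the 14932 probe sets the effects at the 2 ages, which share no array, correlated with r = 0.06 (Spearman rho 0.08, covariance 0.00628). Genes are not independent replicates, and the jackknife standard error over arrays was 0.0697. Ccn2 and both Dmd probe sets were called in the same direction at both ages (1 higher and 2 lower, against 0.0277 and 0.0455 for independent lists), and 0 were called in opposite directions. Of the 343 probe sets called at 8 weeks 171 had the same sign at 10.5 months, and of the 7 called at 10.5 months all 7 had the same sign at 8 weeks.

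With age in control hearts Cpxm2, a carboxypeptidase-like gene, rose from 294 ± 60.6 to 1668 ± 224, 5.24-fold (log2 2.39 ± 0.20, adjusted p = 3.03e-04). Prkcq, which encodes a protein kinase C, rose from a signal below the offset (18.3 ± 4.0) to 240 ± 79.2 (2.40 ± 0.35, adjusted p = 0.0137). This log2 size depends on the offset, so no fold is given. The Z-disc gene Myot rose 3.00-fold (1.59 ± 0.22, adjusted p = 0.00978), the ketone body enzyme gene Bdh1 2.31-fold (1.21 ± 0.19, adjusted p = 0.0230) and the amylase gene Amy1 3.74-fold (1.90 ± 0.25, adjusted p = 0.00922). Six3, Bbip1, Efemp1 and Acsl6 rose by 0.87 to 1.23 (adjusted p = 0.0191 to 0.0230). Ndrg4 fell by 1.44 ± 0.14 (adjusted p = 6.29e-04), Acta2 by 1.16 ± 0.14 (adjusted p = 0.00505), Cngb3 by 1.14 ± 0.15 (adjusted p = 0.00922) and Ddc by 1.09 ± 0.18 (adjusted p = 0.0254). The superoxide dismutase gene Sod1 fell by 1.32 ± 0.21 (adjusted p = 0.0230), but its other tested probe set had the opposite sign. Dmd and Utrn were at 0.30 ± 0.20 and 0.29 ± 0.16 (adjusted p = 0.597 and 0.490).

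Camera called 7 of 35 lists with age in controls, against 0 with an estimated correlation and 1 by fry, the erythroid list. Among the called lists, hypertrophy and fetal genes were higher in older controls (9 of 10 positive, median 0.47, adjusted p = 0.00782, adjusted p = 0.412 with an estimated correlation). By limma 0 members passed over all probe sets and 4 adjusted over the list alone, Nppb (0.61 ± 0.18), Nppa (0.98 ± 0.31), Acta1 (0.68 ± 0.23) and the slow myosin gene Myh7 (0.92 ± 0.33). All 8 atrial markers were positive (median 0.94, adjusted p = 0.00782, adjusted p = 0.549 with an estimated correlation), and none passed. Both lists, which share Nppa and Myl4, moved with the 2 older controls with high Myl7 and Sln. Without both arrays, which leaves 1 older control array, the hypertrophy list had a median of 0.13 (adjusted p = 0.543) and the atrial list one of -0.71 (adjusted p = 0.00202), and without control replicate 1 the adjusted p were 0.0568 and 0.186. The atrial median was 1.49 without control replicate 3 at 10.5 months. With the atrial covariate the medians were 0.31 and 0.08 (adjusted p = 0.0820 and 0.666). Markers of granulocytes and mast cells were lower (median -0.47, adjusted p = 0.0225, adjusted p = 0.412 with an estimated correlation). Of its 8 genes 0 passed over all probe sets and 3 adjusted over the list alone, the neutrophil genes S100a9 (-2.42 ± 0.46), S100a8 (-2.30 ± 0.46) and Ngp (-0.53 ± 0.18). All 4 erythroid genes were negative (median -0.54, adjusted p = 0.0225, adjusted p = 0.412 with an estimated correlation, adjusted p = 0.0166 by fry), with 0 over all probe sets and Slc4a1 (-1.47 ± 0.34) adjusted over the list alone. The granulocyte call was lost without control replicate 1 or 2 at 8 weeks (adjusted p = 0.0731 and 0.0943), and the erythroid call without control replicate 2 at 8 weeks or 1 at 10.5 months (adjusted p = 0.0602 and 0.0568), with a median of -0.35 without control replicate 3 at 8 weeks. Both calls were also lost after quantile normalization (adjusted p = 0.0721 for each), with the range block (0.0854 for each) and with no filter, where the medians were -0.15 and -0.20 (0.110 and 0.248). The erythroid call was lost too with the atrial covariate, without the atrial-rich controls and with the mean of a gene's probe sets (0.0521, 0.0541 and 0.0528).

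Oxidative phosphorylation genes (53 of 56 negative, median -0.27, adjusted p = 1.82e-04, adjusted p = 0.804 with an estimated correlation), glycolysis genes (21 of 24 negative, median -0.26, adjusted p = 0.0142, adjusted p = 0.549 with an estimated correlation) and sarcomere genes (19 of 19 negative, median -0.21, adjusted p = 0.0375, adjusted p = 0.804 with an estimated correlation) were lower in older controls, but after quantile normalization the medians were -0.05, -0.11 and 0.05. No member passed over all probe sets, and only Tmod1 (-0.65 ± 0.16) of the sarcomere list passed adjusted over the list alone. Sdhc (-0.49 ± 0.17) and Pdk1 (0.56 ± 0.19) came nearest in the other lists. These calls were lost without control replicate 2 at 8 weeks, an array of wide signal range (medians -0.06, -0.08 and 0.08), and the sarcomere call also without control replicate 1 or mdx replicate 3 at 10.5 months (adjusted p = 0.108 and 0.0531). Without control replicate 1 at 8 weeks oxidative phosphorylation and sarcomere genes had medians of -0.42 and -0.39. With the range block the medians of the 3 lists were -0.05, -0.14 and 0.05 (adjusted p = 0.717, 0.178 and 0.998). Glycolysis and sarcomere genes lost their calls with no filter (0.0541 and 0.122) and without the atrial-rich controls (0.0541 and 0.202), and sarcomere genes with the atrial covariate (0.0820) and the mean of a gene's probe sets (0.0528). In all 22 probe sets were called, 14 higher and 8 lower, and 1819 had an unadjusted p below 0.05. The count was 7 without control replicate 1 at 8 weeks, 12 and 11 without control replicates 1 and 2 at 10.5 months and 0 without both, and 35 and 34 without mdx replicates 1 and 2 at 8 weeks.

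With age in mdx hearts, Cpxm2 rose 7.35-fold (log2 2.88 ± 0.20, adjusted p = 3.08e-05), Bdh1 5.25-fold (2.39 ± 0.19, adjusted p = 5.03e-05) and the matrix gene Thbs4 4.55-fold (2.19 ± 0.27, adjusted p = 0.00107). Cklf rose by 2.40 ± 0.49 (adjusted p = 0.0107), and Abat by 2.27 ± 0.32 (adjusted p = 0.00209) with its other probe set of opposite sign. Abat rose from a signal below the offset (9.7 ± 6.1), so its size depends on the offset, with 2.86 at an offset of 16 and 1.38 with a floor of 64. The interferon-inducible GTPases fell, Irgm2 by 2.95 ± 0.29, Iigp1 by 2.91 ± 0.24 and Igtp by 2.62 ± 0.24 (adjusted p = 2.20e-04, 5.03e-05 and 1.49e-04). Serf1 fell by 2.62 ± 0.35 (adjusted p = 0.00168), with its other probe set of opposite sign, and Prpf40b by 2.55 ± 0.33 (adjusted p = 0.00115). Dmd and Utrn were at 0.09 ± 0.20 and 0.06 ± 0.16 (adjusted p = 0.792 and 0.832). Dmd was at -0.13 without mdx replicate 3 at 8 weeks and -0.01 without mdx replicate 2 at 10.5 months, and Utrn at -0.06 without mdx replicate 1 at 10.5 months and -0.00 with the range block.

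Of 19 interferon response genes 18 were negative with age in mdx hearts (median -0.76, adjusted p = 5.90e-04, adjusted p = 0.665 with an estimated correlation). Of these 5 passed over all probe sets against 9 adjusted over the list alone, among them Igtp, Stat2 (-0.94 ± 0.21), Irgm1 (-0.95 ± 0.25) and Irf9 (-0.90 ± 0.25). Of 15 fibroblast genes 5 rose over all probe sets and 7 adjusted over the list alone (median 0.20, adjusted p = 0.0166, adjusted p = 0.438 with an estimated correlation), among them Dpt (1.05 ± 0.17), Lum (1.17 ± 0.19), Mfap5 (1.27 ± 0.23) and Meox1 (0.95 ± 0.20). Of 10 hypertrophy genes Acta1 (1.82 ± 0.23), Ccn2 (0.81 ± 0.18), Rcan1 (0.71 ± 0.17) and Nppb (0.73 ± 0.18) rose, 4 over all probe sets and 4 adjusted over the list alone (median 0.50, adjusted p = 0.0170, adjusted p = 0.438 with an estimated correlation). Of 8 complement genes 3 rose over all and over the list alone, Serping1 (0.87 ± 0.18), C1ra (1.30 ± 0.29) and C1s1 (0.84 ± 0.24) (median 0.47, adjusted p = 0.0166, adjusted p = 0.438 with an estimated correlation). Of 21 cell cycle genes 4 rose over all probe sets and 5 adjusted over the list alone, with Mcm3 (1.60 ± 0.26), Cdk4 (0.69 ± 0.16), Pcna (0.65 ± 0.16) and H2az1 (1.13 ± 0.33) (median 0.30, adjusted p = 0.0212, adjusted p = 0.438 with an estimated correlation).

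Of 13 clock genes 1 rose and 4 fell over all probe sets, and 1 rose and 8 fell adjusted over the list alone, with Tef (-1.18 ± 0.20), Cry2 (-1.67 ± 0.36), Arntl (0.98 ± 0.22) and Nr1d1 (-0.82 ± 0.20) (median -0.54, adjusted p = 0.0166, adjusted p = 0.438 with an estimated correlation). Of 16 ion channel genes 2 fell over all probe sets and 4 adjusted over the list alone, Kcnd2 (-0.88 ± 0.15), Kcnk3 (-0.62 ± 0.16), Kcnj11 (-0.87 ± 0.27) and Cacna1h (-0.46 ± 0.15) (median -0.35, adjusted p = 0.0166, adjusted p = 0.438 with an estimated correlation). All 6 ventricular markers were negative (median -0.42, adjusted p = 0.0291, adjusted p = 0.438 with an estimated correlation). Over all probe sets 1 passed, and 3 did adjusted over the list alone, Kcnd2, the cardiac myosin gene Myh6 (-0.94 ± 0.32) and Kcnip2 (-0.52 ± 0.20). Of 29 fatty acid oxidation genes 26 were negative (median -0.37, adjusted p = 0.00953, adjusted p = 0.728 with an estimated correlation). Over all probe sets and over the list alone Acot1 fell (-1.71 ± 0.34) and Acot2 rose (0.64 ± 0.16). Sarcomere genes (median -0.38, adjusted p = 0.0146) and oxidative phosphorylation genes (median -0.30, adjusted p = 0.0170) were lower, each with adjusted p = 0.892 with an estimated correlation, but after quantile normalization the medians were -0.03 and 0.03. Tmod1 (-0.54 ± 0.16) was their only member to pass over all probe sets, and 0 passed by limma adjusted over the list alone.

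Of these 11 lists, sarcomere, oxidative phosphorylation, fatty acid oxidation and interferon genes did not pass by fry (adjusted p = 0.376, 0.598, 0.171 and 0.0891), and the others did. The calls depended in part on single arrays. Without mdx replicate 1 at 8 weeks, of wide signal range and the highest Gapdh ratio, the calls for sarcomere (adjusted p = 0.363), oxidative phosphorylation (0.976), fatty acid oxidation (0.142) and ventricular genes (0.189) were lost. Their medians were then -0.15, -0.03, -0.20 and -0.39. Without mdx replicate 2 at 8 weeks these same lists (0.0735, 0.302, 0.0579 and 0.0844), ion channels (0.0639) and the cell cycle (0.102) were lost, and without mdx replicate 3 hypertrophy (0.10) was lost. Without mdx replicate 3 the medians for sarcomere, oxidative phosphorylation, fatty acid oxidation and ventricular genes were -0.78, -0.66, -0.64 and -0.78. Without mdx replicate 1 at 10.5 months oxidative phosphorylation (0.262) and ventricular genes (0.0622) were lost, without mdx replicate 2 oxidative phosphorylation (0.0870) and the cell cycle (0.0618), and without mdx replicate 3 complement (0.0754), ion channels (0.0735) and the cell cycle (0.0749). With the range block sarcomere, oxidative phosphorylation and ventricular genes were lost (0.165, 0.980 and 0.108), and with no filter oxidative phosphorylation (0.0967). The lists of interferon, fibroblast and clock genes kept their calls without any single array, but not their size. Without mdx replicate 3 at 8 weeks the interferon median was -0.39 and the fibroblast median 0.53, and without mdx replicates 1 and 2 at 10.5 months the latter was 0.38 and 0.10.

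In all 1706 probe sets changed with age in mdx hearts, 814 higher and 892 lower, for 1430 genes, of which 209 and 224 changed at least 2-fold, and 4512 had an unadjusted p below 0.05. Of the 64 Affymetrix control probe sets, 20 had an unadjusted p below 0.05 here and 1 was called, against 1 to 7 and 0 in the other comparisons. A technical difference between the mdx arrays of the 2 ages is therefore not excluded as part of this count. The 5th percentile of deposited signal was 24.3 to 34.9 on the 8-week arrays and 17.6 to 22.6 on the 10.5-month arrays, controls included. A technical difference between ages is thus not excluded for the controls either. Of 752 called genes with another tested probe set, the brightest of the others moved in the same direction in 538 (share 0.715, exact 95% interval 0.682 to 0.747). These others moved by a median of 0.211 in the called direction, against a median size of 0.791 for the called probe sets, which were picked by their p-value. The count was 598 and 858 without mdx replicates 2 and 3 at 10.5 months, 985 without both atrial-rich controls, and 565 when only mdx arrays were fitted. The age effects in control and mdx hearts, which share no array, correlated across genes with r = 0.40 (Spearman rho 0.41, covariance 0.0558). Of the 22 probe sets called in controls 18 were called in the same direction in mdx hearts, 11 higher and 7 lower, against 0.763 and 0.478 for independent lists, and 0 in the opposite direction. Among them were Cpxm2, Bdh1, Myot, Prkcq, Amy1, Efemp1 and Acsl6 with rises and Ndrg4, Sod1, Cngb3 and Ddc with falls. A technical difference between ages would enter both age effects alike, so neither the correlation nor the shared calls tell it apart from ageing.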

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

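Of the tests below, those of lower atrial expression in mdx hearts, of the atrial share behind Nppa, and of the signal range behind the sarcomere and oxidative phosphorylation lists were chosen only after the results were seen. The results in this part stand out because the effect of mdx differed between the 2 ages, by a test of the difference itself (10.5 months minus 8 weeks). This held for 23 probe sets. Among the genes named, the difference was 1.83 for Tpd52l1, 1.77 for P2ry1, 1.505 for Mpg, 1.47 for Ints3 and 1.44 for Acta2, of which P2ry1 and Mpg did not pass with a floor of 64. It was -2.76 for Prpf40b, -2.37 for Iigp1, -2.04 for Aanat, -1.99 for Igtp and -1.64 for Six3 (adjusted p = 0.0196 to 0.0427). Only 7 of these 10 genes passed with a floor of 64. The lists that differed were the interferon response (median -0.58), the cell cycle (0.13), the clock (-0.74) and atrial markers (-1.15), each with adjusted p = 0.911 with an estimated correlation. With single arrays left out the interferon median ran from -0.79 to -0.26.

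The 8-week mdx arrays correlated with arrays of other groups at 0.923 to 0.958 (median 0.939) and with each other at 0.948 to 0.957, against 0.936 to 0.979 (median 0.9655) between the other groups. They gave 343 called probe sets, and the 10.5-month mdx arrays gave 7. With array weights these counts were 191 and 110, and with only the compared groups in the fit 23 and 5. The contrast in counts therefore depends on how the spread is estimated. Single probe sets behaving differently on the 8-week mdx arrays remain possible as part of the cause. The brightest other probe set of a called gene moved in the same direction in a share of 0.649 (exact 95% interval 0.573 to 0.720). This lies under the bound of 0.75 written for that explanation but above the 0.5 of chance, which the same prediction also named. In size the others moved by a median of 0.11 in the called direction, against 0.914 for the called probe sets, which were picked by their p-value. The first version of this test used the 2 brightest probe sets of each gene, gave 0.702 (92 of 131), and decided nothing; it was replaced because it differed from the written prediction. Adjusting for a wide signal range did not take the calls away. With that range as a block 350 probe sets were called, 275 of them among the 343, and the called effects kept a median fraction of 0.991. After quantile normalization 456 were called, 313 of them among the 343. The block called 312 probe sets for the range itself. It is yes or no for each array, and at 8 weeks it leans on control replicate 2 and mdx replicate 3. A graded effect of the range therefore stays open as part of the cause. The written test rests on 1 array and excludes nothing alone: mdx replicate 3, of ordinary range, showed a median share of 0.659 of the effect (95% interval 0.583 to 0.745) on 212 probe sets called without it, where simulation without a mdx effect gave 0.172 to 0.336. A young-heart response in mdx remains open.

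Among 10000 random lists of equally bright genes, 92.92% had a smaller median over both ages than the sarcomere list and 79.47% a smaller one than the oxidative phosphorylation list, and at 10.5 months the latter share was 99.1%. The bounds written for a wide signal range, which concern both ages together, held the first 2 values, while the value at 10.5 months lies outside them.

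Clock genes that were lower in mdx hearts at 10.5 months could come from hearts of the 2 genotypes collected at different times of day. The bound written for that explanation was met, since the 3 opposite-phase genes (mean 0.35) and 8 output genes (mean -1.07) differed by 4.839 standard errors across genes, and 4.846 at 8 weeks. It was first read as bearing the explanation out, and that reading was dropped after the value was seen, because the output genes are the low genes that prompted the test. Standard errors across genes of the same arrays do not measure the spread between samples. The opposite-phase genes alone were 1.43 standard errors above 0 at 10.5 months (3.74 at 8 weeks), too little for 3 genes to decide, so different times of collection stay open. An effect of mdx on the clock itself would look alike and remains open too, because times of collection were not given in the sources used here.

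Atrial markers were high on control arrays 1 and 2 at 10.5 months. More atrial tissue in those samples predicted that the other markers move too, and their median log2 difference from control 3 was 1.902, with fold differences of 11.7 for Myl4, 5.71 for Bmp10 and 1.13 for Kcnj3. Lower atrial expression in mdx hearts stays open. The bound written against it was met, as 1 of 3 control arrays lay below the median mdx array, and it was first read as excluding this; that reading was dropped after the value was seen, because the bound was wrong to let a single array decide. For Nppa, the atrial score as a covariate argued against a different atrial share as the whole cause, without excluding it. Its rise over both ages was 1.199 ± 0.154 with the score (adjusted p = 0.00920), against 1.01 ± 0.22 without (adjusted p = 0.0971, not called). At 10.5 months alone it was 1.39 ± 0.25 with the score (adjusted p = 0.150). The score includes Kcnj3 and Stard10, which were only 1.13-fold and 1.23-fold higher on the 2 control arrays, so it measures the atrial share imprecisely.

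For mdx at 8 weeks, the true grouping was compared with the other ways of dividing the same arrays. There are only 10 such splits of 3 against 3, too few for a test, and 2 of them gave at least 343 calls. The other gave 471, and it parted the arrays of wide range (control 2, mdx 1 and mdx 2) from the rest, so it points to structure that follows the signal range; with that range as a block the mdx count was 350. Splits were also too few at 10.5 months (1 of 10, highest other 2, real 7), for age in controls (1 of 10, highest other 1, real 22) and for age in mdx hearts (1 of 10, highest other 1, real 1706). Over both ages 1 of 100 splits gave as many calls as the real 30 (highest other 17), and for the difference between ages 2 of 100 gave at least 23 (highest other 27).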

How the results depend on the processing

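The signal range block, the atrial score covariate and the fit without the 2 atrial-rich control arrays were chosen only after the results were seen. Signal over background limits the genes tested, since 14932 probe sets reached the filter, and changes of dim genes are understated by the offset. No named gene that passed in a comparison, over all probe sets or its list alone, changed sign there in any setting. Among genes that did not pass, Utrn at 8 weeks and Dmd and Utrn with age in mdx hearts did. Each control or mdx array left out in turn leaves 2 arrays in its group, and without the atrial-rich arrays 1 control array is left at 10.5 months, so that setting bears out no call. The cause of a changed value was not tested, except that fewer arrays, fewer tested probe sets or a wider threshold change counts by construction.

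The 343 probe sets of mdx at 8 weeks became 163 with a filter at 300, 191 with array weights, 23 with only the 8-week arrays, 150 with the atrial covariate, 93 without the atrial-rich arrays and 692 at adjusted p under 0.10. Leaving out single arrays gave 42 to 308. The 7 of mdx at 10.5 months became 11 with trend and robust, 110 with array weights, 0 with the atrial covariate, 0 without the atrial-rich arrays and 13 at adjusted p under 0.10 (single arrays left out, 1 to 12). The 30 over both ages became 46 with trend and robust, 100 with array weights, 8 without the atrial-rich arrays and 85 at adjusted p under 0.10 (12 to 60). The 23 for the difference became 10 with a filter at 300, 141 with array weights, 3 with the atrial covariate, 4 without the atrial-rich arrays and 76 at adjusted p under 0.10 (0 to 31). The 22 for age in controls became 42 with a filter at 300, 59 with trend and robust, 270 with array weights, 7 with only control arrays, 12 with the atrial covariate, 0 without the atrial-rich arrays and 67 at adjusted p under 0.10 (7 to 35). The 1706 for age in mdx hearts became 565 with only mdx arrays, 1041 with the atrial covariate, 985 without the atrial-rich arrays and 3028 at adjusted p under 0.10 (598 to 1883). The correlation of mdx effects, 0.06486, became -0.02971 with the atrial covariate, 0.02344 with array weights, 0.03451 with no filter and 0.03769 after quantile normalization (0.01237 to 0.09278). Apart from the replicate blocks given next, the remaining settings left each count within 1.5 times its value.

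The replicate numbers were not taken as pairs, because the 12 correlations between samples of the same number ran from -0.129 to 0.135, 2 were over 0.1 and 4 of 12 samples correlated best with their own number. With the number as a replicate block the counts were 176 and 3 for mdx at 8 weeks and 10.5 months, 10 for the difference, 28 over both ages, 18 for age in controls and 1529 in mdx hearts, and 47 lists passed. With a block within each age the counts were 101, 3, 9 over both ages and 0 for the difference.

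Of 46 list calls 0 held with an estimated correlation. By fry 11 lists passed, 9 of them among the 46, and single arrays left out gave 35 to 50 lists, 35 to 45 of them among the 46. After quantile normalization the direction turned for oxidative phosphorylation (8 weeks -0.0782, 10.5 months 0.0192 by the test although the median stayed positive, both ages -0.0167, age in mdx 0.0322) and for sarcomere genes (both ages -0.0231, age in controls 0.0537). The signal range block turned oxidative phosphorylation at 8 weeks (-0.0148) and over both ages (0.000556, by the test only). Sarcomere medians also changed sign at 8 weeks after quantile normalization (-0.0153) and for age in controls with the range block (0.0476). Single arrays left out gave -0.0225 (without mdx replicate 1) to 0.559 for oxidative phosphorylation at 8 weeks, and -0.385 to 0.0778 (without control replicate 2 at 8 weeks) for the sarcomere list in ageing controls. The atrial list turned with the atrial covariate (10.5 months 0.00475, difference 0.0527) and without the atrial-rich arrays (10.5 months 0.695, difference -7.83e-06 by the test only, age in controls -0.715), by construction.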

Other observations

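No test in this part was chosen only after its result was seen. With age in mdx hearts single genes changed in lists that did not pass. Of 14 genes of the dystrophin glycoprotein complex 1 rose and 2 fell over all probe sets, and 2 rose and 3 fell adjusted over the list alone, among them the nitric oxide synthase gene Nos1 (-0.82 ± 0.18), the dystroglycan gene Dag1 (-0.75 ± 0.21) and Sgca (0.53 ± 0.15). Of 16 integrin and costamere genes 3 fell, among them the cytolinker gene Plec (-0.97 ± 0.20). Of 17 calcium handling genes 2 fell over all probe sets, Itpr2 (-1.72 ± 0.24) and the ryanodine receptor gene Ryr2 (-0.92 ± 0.21), and Asph (0.41 ± 0.13) rose adjusted over the list alone. Of 42 matrix genes 4 rose, among them Thbs4 (2.19 ± 0.27) and Timp2 (0.69 ± 0.17). The natriuretic peptide clearance receptor gene Npr3 was higher with age in mdx hearts (0.80 ± 0.20) and, adjusted over the list alone, in controls (1.01 ± 0.20).

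Lists not called for mdx at 8 weeks and at 10.5 months are given with their medians and adjusted p at the 2 ages in turn. They were the dystrophin glycoprotein complex (-0.09, 0.386 and -0.14, 0.281), integrins and costameres (0.05, 0.870 and -0.03, 0.469), antigen presentation (0.02, 0.921 and -0.09, 0.651), fatty acid oxidation (0.17, 0.199 and -0.04, 0.434), glycolysis (-0.10, 0.321 and 0.05, 0.885) and calcium handling (0.05, 0.870 and -0.12, 0.344). Neurohormonal signalling (-0.00, 0.354 and -0.11, 0.469), heat shock (0.08, 0.902 and 0.09, 0.185), antioxidants (0.01, 0.870 and 0.05, 0.469), p53 targets (-0.01, 0.902 and 0.10, 0.185), atrophy and autophagy (-0.04, 0.668 and -0.12, 0.469), the cell cycle (-0.17, 0.138 and 0.07, 0.238) and immediate early genes (0.00, 0.668 and -0.07, 0.885) followed. Cell types without a call were lymphocytes (0.27, 0.354 and -0.10, 0.775), granulocytes and mast cells (-0.13, 0.902 and 0.11, 0.469), smooth muscle (-0.13, 0.320 and -0.22, 0.440), ventricular myocytes (0.29, 0.354 and 0.01, 0.862), adipocytes (-0.10, 0.614 and -0.12, 0.739), erythroid cells (-0.23, 0.614 and -0.22, 0.343), lung (0.02, 0.742 and 0.07, 0.783), nerve and Schwann cells (0.12, 0.298 and -0.01, 0.922) and sex genes (0.04, 0.902 and -0.04, 0.912). Lists called at 1 age only had, at the other, 0.14 (0.185) for the sarcomere, -0.04 (0.752) for interferon and 0.09 (0.344) for chemokines at 10.5 months. At 8 weeks they had 0.51 (0.138) for hypertrophy, 0.15 (0.138) for matrix, -0.06 (0.902) for complement, 0.00 (0.902) for ion channels, 0.17 (0.321) for macrophages, 0.11 (0.558) for fibroblasts, -0.20 (0.0785) for endothelium and 0.54 (0.284) for atrial markers. Medians without a test were 0.03 and -0.15 for skeletal muscle regeneration, 0.04 and 0.22 for fast skeletal muscle, and 0.36 and 0.01 for thymus and lymph node.

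The brightest probe set of Xist had mean signals of 173 to 210 in the 4 groups, its 2 other probe sets were near the floor (10.4 to 28.2 and 2.77 to 14.05), and the Y-linked gene Eif2s3y had 345 to 438. Among the 64 Affymetrix control probe sets 1 was called with age in mdx hearts and 0 in the other comparisons by limma, with 20, 7, 2, 5, 1 and 2 at an unadjusted p below 0.05 for age in mdx hearts, mdx at 8 weeks, at 10.5 months, over both ages, the difference and age in controls. The first 2 principal components held 30.0% and 14.2% of the variance.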
